A study of Homo sapiens with 6 samples.

How the data were processed

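MicroRNA levels were measured in total RNA of 2 lines of human lung adenocarcinoma cells, 3 samples of the parental line H1975 and 3 of its osimertinib-resistant derivative H1975_OR, each on its own single-colour array with Cy3 label. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the resistant cells were made by rounds of rising osimertinib, each of 72 h, with recovery between rounds, and RNA was extracted with Trizol. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

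Per the file headers, the authors deposited scanner output of Agilent Feature Extraction 11.0.1.1, in which intensity values on a linear scale had been background-subtracted per spot and had not been normalized between arrays. The other columns used were detection, outlier, saturation and control flags, which Agilent's software sets, and raw pixel medians of spot and local background. The authors also deposited a table of log2 values per miRNA, whose steps are not given in the sources used here. Against log2 of each array's summed signal per miRNA its columns had correlations across miRNAs of 0.993 to 0.996, they shared a maximum of 15.7, and their medians were -3.32, -3.30, -3.30, -2.96, -3.14 and -3.19. The scale and direction of that table were settled by this comparison, and its normalization, which resembles quantile normalization, stays inferred.

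Each array held 50980 spots, 5893 probes and 2549 human miRNAs, with a median of 20 spots per miRNA. Spots marked as outliers (3.14% to 3.48% of each array) and control spots were left out, and no spot was saturated. Processed signals were averaged over the spots of a probe and then over the probes of a miRNA on the linear scale, divided by the array's 75th percentile over the 853 miRNAs detected on all 6 arrays, raised to a common floor of 0.0253 (-5.30 on the log2 scale, the highest over arrays of the lowest scaled value of a detected miRNA) and converted to log2. The floor replaced 0.985% of the values of the tested miRNAs. Among the 647 called miRNAs with at least 2 measured probes, 20 had probes that moved in opposite directions. A miRNA was tested if the detection flag was set on all 3 arrays of at least 1 group, which left 998. The number of arrays limits the precision, and the median within-group SD was 0.065 on the log2 scale.

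The contrast H1975_OR minus H1975 was fitted with limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3 with the package data.table (version 1.17.8), and a miRNA was called at a Benjamini-Hochberg adjusted p under 0.05. For miRNAs detected on all arrays of 1 group and on none of the other, a lower bound of the fold is given: the mean of the bright group against, per array of the dim group, the higher of the lowest scaled signal among miRNAs well above background and the miRNA's own value. This bound makes no allowance for the spread between arrays. The 30 lists of miRNAs were fixed before the data were examined, and the 27 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which does not compare a list with other miRNAs. Single values per array were compared with an exact two-sided permutation test, for which 3 against 3 arrays cannot give a p below 0.1. Arms of hairpins and neighbouring genes were compared with 10000 random draws.

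The miRNAs named were those with the 10 highest and 10 lowest changes among called miRNAs detected on all 6 arrays with no overlap of the groups, up to 10 detected in 1 group only in order of signal, up to 4 called members per list by size of change, 8 miRNAs chosen in advance, and the 5 brightest. Other miRNAs named were chosen after their values were seen, as is said where they stand. Gene symbols came from a RefSeq table of assembly GRCh38.p14, while the arrays' grid names hg19, so no coordinates are printed. The table served for names, chromosomes, the order of genes and whether neighbours started under 10 kb apart. Of the tested miRNAs, 915 matched 1 gene, 65 several and 18 none.

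The fit was tested on simulated data with the means and spreads of the 998 miRNAs, 200 of them changed, in 20 simulations. With the array factors known, 4.86% of calls were false on average, and changes of 0.25, 0.5, 1 and 2 on the log2 scale were recovered in 74.9%, 95.1%, 99.6% and 100% of cases. With scaling on the 75th percentile the recovered shares were 70.8%, 95%, 99.6% and 99.6%, but the share of false calls averaged 19.9% and reached 71.9% in 1 simulation. The changed miRNAs themselves moved the percentile, by which every other miRNA was offset by -0.14 to 0.0092. With no miRNA changed, both ways of scaling called 0.1 miRNAs on average. Simulated changes placed in both groups gave offsets of -0.11 to 0.059. The list test was tried in 1 simulated data set of 998 miRNAs drawn independently of each other. It called the 1 list of 20 that was shifted by 1.2 on the log2 scale and no other. Estimated correlations were 0.090 to 0.59 in the lists called below, so this trial does not show how often such lists are called falsely.

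Alternatives fixed before the data were examined covered the percentile and the kind of scaling, the background correction, the summary per miRNA, the authors' log2 table, the floor, the detection filter and flag, the moderation of variances, replicate number or slide as a block, each array left out, the set tests and the arms used. The normexp alternative (offset 50) used pixel medians of the spots where pixel means had been planned. Arrays of slide 1 alone, scaling on control probes, a test of the lists among miRNAs numbered under 1000 only, the comparison of the miR-200 clusters and a separate count of neighbours under 10 kb apart were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.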

Results

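H1975 is a human lung adenocarcinoma cell line with mutant EGFR, and osimertinib is an inhibitor of the EGFR kinase. The arrays compared H1975 with H1975_OR, a derivative made resistant to osimertinib, to describe which miRNAs differ between them. Of 2549 human miRNAs on the array, 1052, 1016 and 1021 were detected in the H1975 replicates and 864, 934 and 954 in the H1975_OR replicates. The lowest correlation across miRNAs was 0.999 between H1975 arrays and 0.997 between H1975_OR arrays, and the highest between the groups was 0.968. The 3 H1975 arrays and H1975_OR replicate 1 shared slide 1, and H1975_OR replicates 2 and 3 were on slide 2. Per the file headers, H1975_OR replicate 3 had another scan date than all other arrays. All changes below are H1975_OR minus H1975 on the log2 scale, relative to each array's 75th percentile, from limma with n = 3 per group.

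The resistant cells had higher levels of the miRNAs of the miR-200b cluster and lower levels of miR-1246, miR-137 and miR-26b-5p. The highest change was that of miR-200b-3p at 2.14 (SE 0.040), followed by miR-4697-5p at 2.11, miR-200a-3p at 1.96 and miR-429 at 1.90. miR-3654 at 1.71, miR-6785-5p at 1.67, miR-4647 at 1.58, miR-6132 at 1.53 and miR-4636 at 1.52 also rose. miR-146a-5p, a miRNA induced by NF-kB signalling, rose by 1.39 (SE 0.064). Among these 10 miRNAs the adjusted p of limma was at most 2.88e-06.

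The lowest change was that of miR-1246, whose sequence matches part of the U2 small nuclear RNA, at -2.67 (SE 0.071). miR-137, a miRNA of neural cells, was at -2.34 (SE 0.045) and miR-26b-5p at -2.16 (SE 0.040). The others among the 10 lowest of the miRNAs detected on all 6 arrays were miR-8089 at -2.13, miR-3934-5p at -1.87, miR-374a-5p at -1.86, miR-365b-5p at -1.78, miR-1290 at -1.73, miR-590-5p at -1.65 and miR-362-3p at -1.63. Their adjusted p in limma was at most 5.85e-06.

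Detection in 1 group only was found for 59 miRNAs in H1975 and for 4 in H1975_OR. Detection flags are set before scaling, and the H1975_OR arrays were dimmer (917 detected miRNAs on average, against 1030 in H1975). A lower bound of the fold was above 1 for 51 of these 63, and the other 12 have none. For 21 of the 51 it equals the fitted change. Of the 10 brightest, 9 were detected in H1975 alone: miR-205-3p at least 2.68-fold higher there, miR-6805-5p at least 2.41-fold, miR-28-3p at least 2.84-fold, miR-3692-5p at least 2.01-fold, miR-33a-5p at least 2.51-fold, miR-454-3p at least 2.31-fold, miR-3065-5p at least 2.08-fold, miR-6835-5p at least 2.03-fold and miR-628-5p at least 1.94-fold. miR-4659a-3p was detected in H1975_OR alone and was at least 2.51-fold higher there. For miR-205-3p, miR-6805-5p and miR-4659a-3p the bound equals the fitted change, because the undetected signal itself set it. With normexp 8 of these 9, all but miR-28-3p, turned to changes of 0.0099 to 0.076. The adjusted p of limma for these 10 was at most 0.00296.

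**Figure D1:**
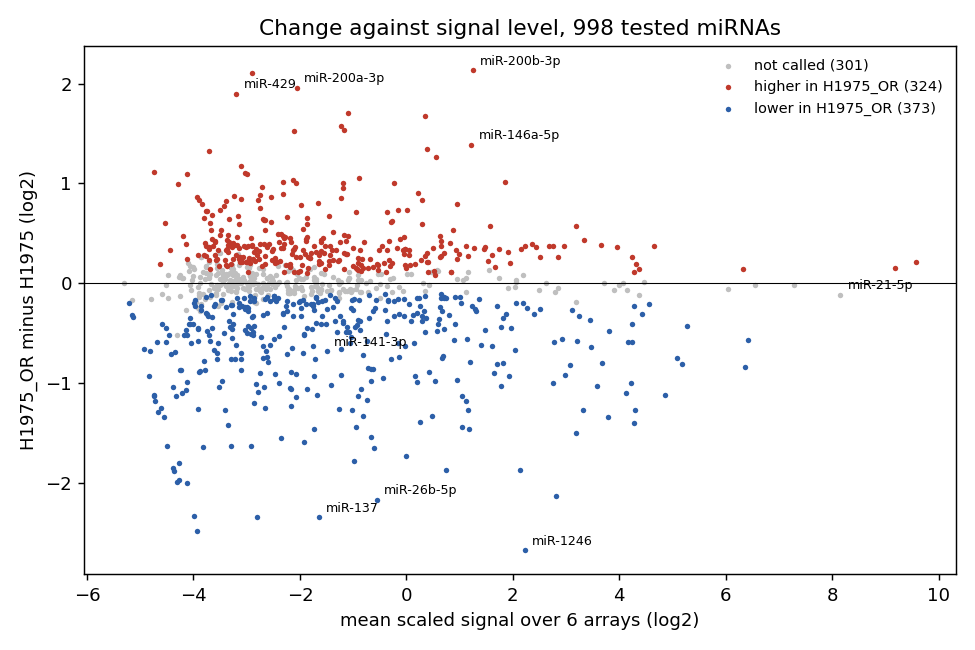
Each point is 1 of the 998 tested miRNAs, with its mean scaled signal over the 6 arrays on the horizontal axis (log2) and its change, H1975_OR minus H1975, on the vertical axis (log2). Red points are the 324 called higher, blue points the 373 called lower and grey points those not called. miR-200b-3p lies highest at 2.14 and, of the named points, miR-1246 lies lowest at -2.67.

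Of the 998 miRNAs tested, limma called 697 (69.8%), 324 higher and 373 lower in H1975_OR, and 719 had an unadjusted p under 0.05. Changes of at least 1 on the log2 scale were called for 25 higher and 76 lower. These counts were 9 and 154 with no scaling, 12 and 131 with bright control probes, 2 and 17 with normexp and 32 and 45 with the brightest probe. Slide 2 held only H1975_OR arrays, so a fit with slide as a block takes every change from slide 1. It compares H1975_OR replicate 1 with the 3 H1975 arrays, as does the fit of slide 1 alone. The median change of the tested miRNAs was -0.042 in both, against -0.020 in the main fit. The balance of higher and lower calls depended on the processing. Among scalings it was 349 and 341 with the median, 333 and 359 with the percentile over all miRNAs, 357 and 323 with quantile normalization, 79 and 626 with bright control probes (median of all miRNAs moved by -0.30) and 71 and 765 with no scaling (-0.41). It was 700 and 206 with normexp background correction (0.13), 380 and 240 with the brightest probe as the summary (0.10) and 467 and 286 with the authors' table (0.13). Small changes are the least certain, because scaling alone moved unchanged miRNAs by up to 0.14 in simulated data. The 95% interval lay beyond that offset for 492 of the 697 calls, 216 higher and 276 lower. The true offset of these arrays is not known. It may be larger than 0.14, because the simulations changed only 200 miRNAs, in random directions, while 697 were called here.

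The miR-200 family, which restrains the epithelial to mesenchymal transition through ZEB1 and ZEB2, is encoded in 2 clusters. Of its 7 tested members 5 rose and 2 fell (the same counts adjusted over the list alone). The 3p arms of the cluster on chromosome 1 rose: miR-200b-3p by 2.14, miR-200a-3p by 1.96 and miR-429 by 1.90. Over 25 alternatives their lowest values were 1.54, 0.60 and 0.30 in this order. Those of the cluster on chromosome 12 were lower, with miR-141-3p at -0.68 (SE 0.048) and miR-200c-3p at -0.60 (SE 0.057), although the value of the dim miR-200c-3p turned to 0.086 with normexp and to 0.70 with the authors' table. The mean of the 3 minus the mean of the 2, taken within each array, was -0.13 ± 0.021 (SD, n = 3) in H1975 and 2.51 ± 0.081 (SD, n = 3) in H1975_OR, a difference of 2.64, a comparison chosen after the changes were seen, for which no test is given. On slide 1 alone, with 1 H1975_OR array, the difference was 2.57. The list as a whole was not past the threshold (camera, adjusted p = 0.0929).

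**Figure D2:**
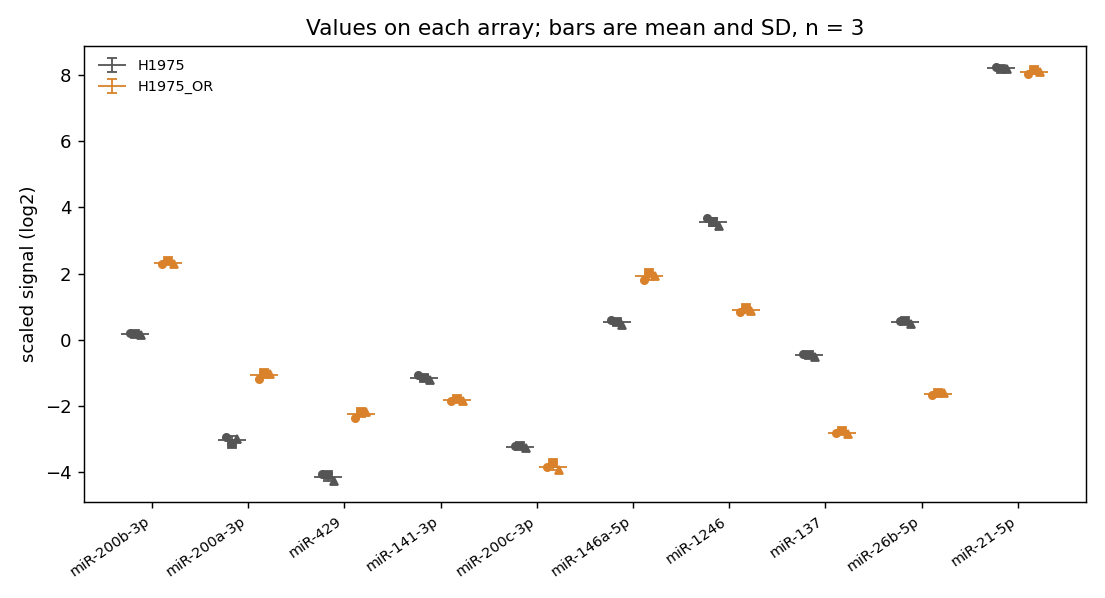
Scaled signals (log2, vertical axis) of 10 miRNAs on each array, with circles, squares and triangles for replicates 1, 2 and 3, horizontal bars for group means and error bars for the SD (n = 3). miR-200b-3p rose by 2.14 and miR-1246 fell by 2.67 with no overlap of the groups, and miR-21-5p differed by -0.11.

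Of the 27 lists tested, 7 were past the threshold with camera at the preset correlation, all 7 lower in H1975_OR. No list was past the threshold with an estimated correlation (adjusted p = 0.612 for each of the 7), and none had an unadjusted p under 0.05 in that test, while 23 of the 27 were past it with fry. Of all tested miRNAs with a registry number under 1000, 189 of 374 fell, and among the brightest 20% of miRNAs 69 of 101 of them fell (median -0.41, against 0.089 for those numbered 1000 or above). Compared only with miRNAs numbered under 1000, a test chosen after the results were seen, none of the 7 was past the threshold (camera, lowest adjusted p = 0.258). The GC-rich list had too few such members to be tested. The p53-induced list was tested there without miR-1246, its lowest member, which left 11. In the miR-17~92 cluster and its paralogs, which MYC activates, 12 of 17 members fell and 1 rose (adjusted p = 0.0241, and adjusted p = 0.612 with an estimated correlation). miR-363-3p, detected on 1 of 3 H1975_OR arrays, was at -2.33, miR-20a-5p at -1.34 and miR-20b-5p at -1.33, while miR-25-5p, detected in H1975_OR alone, was at least 1.91-fold higher there. With normexp 11 of the 17 fell and 4 rose, while 11 fell and 5 rose with the authors' table and 9 fell and 4 rose with quantile normalization. In the miR-15/16 family, which represses cyclins and BCL2, 6 of 8 fell (adjusted p = 0.0274, and adjusted p = 0.612 with an estimated correlation), among them miR-195-5p at -1.44, miR-15b-5p at -1.40 and miR-16-5p at -0.80. In the families of miR-130, miR-301, miR-148 and miR-152 7 of 8 fell and 1 rose (adjusted p = 0.0264, and adjusted p = 0.612 with an estimated correlation), with miR-301a-3p at -1.54 and miR-148b-3p at -1.20, although 4 fell and 1 rose with normexp (the mean moved from -0.97 to -0.24). Of the p53-induced miRNAs 9 of 12 fell and 1 rose (adjusted p = 0.0241, and adjusted p = 0.612 with an estimated correlation), with miR-1246 lowest, then miR-192-3p at -1.09, miR-107 at -0.82 and miR-215-5p at -0.81. The lists overlap: 10 of these 12 are in other lists too, among them all 5 liver and gut markers. Of the miRNAs that the literature links to EGFR inhibitor resistance 12 of 18 fell and 1 rose (adjusted p = 0.0264, and adjusted p = 0.612 with an estimated correlation), such as miR-7-1-3p at -0.87 and miR-34a-3p at -0.73, and 16 of the 18 are in other lists too. With normexp these examples turned to 0.064 and 0.030, and the former to 0.086 with the authors' table. With normexp 7 of the 18 fell and 7 rose (the mean moved from -0.41 to -0.095), and 9 fell and 6 rose with the authors' table. Of the neuroendocrine and neural markers 6 of 8 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p of the list 0.0379, and adjusted p = 0.612 with an estimated correlation), with miR-137 lowest and miR-219a-5p at -0.90 and miR-9-3p at -0.89. With normexp 3 of the 8 fell and 2 rose, the mean moving from -0.83 to -0.067 and miR-219a-5p to 0.029. Of the miRNAs with GC-rich probes, a technical list, 20 of 37 fell and 3 rose (adjusted p = 0.0241, and adjusted p = 0.612 with an estimated correlation), with miR-4739 at -0.76, miR-3960 at -0.62 and miR-1268a at -0.60, although 36 fell and 0 rose with no scaling and 24 fell and 8 rose with normexp. Counts adjusted over the list alone were the same in the other 6 lists. With slide as a block, which rests on the lone H1975_OR array of slide 1, the mean change of the 7 ranged from -1.04 to -0.23. The list calls depended on the processing. Median scaling and the percentile over all miRNAs each called 8 lists (the same 7, and the DLK1-DIO3 cluster as higher). Scaling on control probes called 6. These were the GC-rich, p53-induced, miR-17~92 and miR-15/16 lists, and as higher the miR-200 family and the DLK1-DIO3 cluster. In that setting the DLK1-DIO3 cluster was higher only relative to the other miRNAs, with which camera compares a list, as its mean change was negative. Quantile normalization called 2 (the p53-induced miRNAs and the families of miR-130, miR-301, miR-148 and miR-152). The authors' table called 1 (the p53-induced miRNAs), and no scaling called 2 (the GC-rich list, and the miR-200 family as higher).

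**Figure D3:**
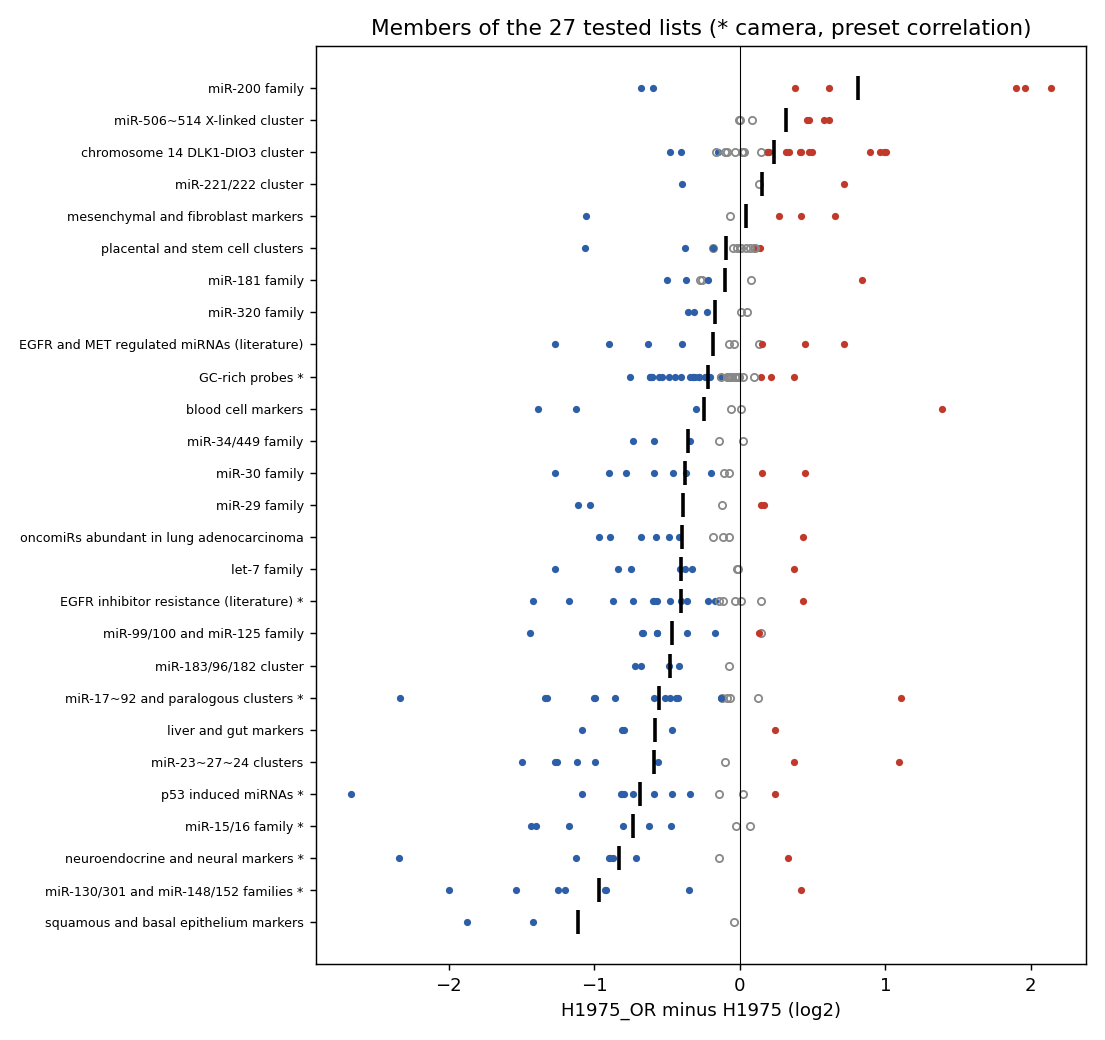
Changes of the members of the 27 tested lists (horizontal axis, H1975_OR minus H1975, log2), with filled points for called members, open points for members not called and a black bar for the mean of each list. An asterisk marks the 7 lists past the threshold with camera at the preset correlation, whose means all lie below 0. With an estimated correlation none of the 27 was past it (lowest adjusted p = 0.612).

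The other lists were not past the threshold as lists, and their members are described by their own tests. In the let-7 family, which represses RAS genes and HMGA2, 6 of 9 fell and 1 rose, with let-7b-5p at -1.27, let-7a-5p at -0.84, let-7f-5p at -0.75 and let-7g-5p at -0.41. These counts depended on the processing, as 4 fell and 3 rose with quantile normalization, the mean change moving from -0.40 to -0.092, and 4 fell and 1 rose with the authors' table. In the miR-232724 clusters 6 of 9 fell and 2 rose, with miR-23b-3p at -1.50, miR-27a-3p at -1.27 and miR-24-3p at -1.12. Of the miR-30 family 7 of 11 fell and 2 rose, with miR-30b-5p at -1.27 and miR-30c-5p at -0.90. Of the miR-99/100 and miR-125 family 7 of 9 fell and 1 rose, with miR-99a-5p at -1.44 and miR-100-5p at -0.57, although 4 fell and 3 rose with the authors' table and 5 fell and 4 rose with normexp. In the cluster of miR-183, miR-96 and miR-182, 4 of 5 fell, with miR-96-5p at -0.72, and of the miR-34 and miR-449 families 3 of 5 fell, although with normexp 2 fell and 2 rose in each (the means moved from -0.48 to -0.089 and from -0.36 to -0.15). Of the miR-29 family 2 of 5 fell and 2 rose, with miR-29c-3p at -1.03 and miR-29a-3p at 0.14, which turned to -0.27 with no scaling, where all 5 fell. In the miR-320 family 3 of 5 fell, although with quantile normalization 2 fell and 2 rose, and in the miR-181 family 3 of 7 fell and 1 rose, its mean change of -0.10 turning to 0.048 with normexp, where 1 fell and 5 rose. Where no other count is given, the counts adjusted over the list alone were the same.

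In the chromosome 14 DLK1-DIO3 cluster 13 of 24 members rose and 3 fell (camera, adjusted p = 0.0593), although the mean of 0.24 turned to -0.17 with no scaling, where 4 rose and 14 fell, and to -0.060 with scaling on control probes. Its members included miR-431-3p at 1.01, miR-299-3p at 0.96 and miR-381-3p at 0.90. In the X-linked cluster of miR-506 to miR-514, 4 of 7 rose, all of the miR-513 group, with miR-513c-5p at 0.61 and miR-513a-5p at 0.58, and the mean of 0.32 turned to -0.098 with no scaling, where 2 rose and 3 fell. Of the placental and stem cell clusters, of chromosome 19 except for miR-302c-5p of chromosome 4, 3 of 14 fell and 2 rose, miR-302c-5p at 0.14 (-0.28 with no scaling) and miR-371b-5p at 0.11 (2 and 2 adjusted over the list alone). Their mean change was -0.092, their median was 0.0048 and camera gave the direction as higher, so no direction is assigned. With no scaling 14 fell, and with normexp 1 fell and 13 rose. Of the EGFR and MET regulated miRNAs 4 of 10 fell and 3 rose, with miR-103a-3p at -0.63, and the mean of -0.19 turned to 0.11 with the authors' table, where 3 fell and 6 rose. Of the oncomiRs abundant in lung adenocarcinoma 6 of 10 fell and 1 rose (7 and 1 adjusted over the list alone), with miR-31-3p at -0.58.

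Among markers of other cell types, 4 of 5 liver and gut markers fell and 1 rose, with miR-192-5p at -0.80 and miR-194-5p at -0.47. Of 3 squamous and basal markers 2 were detected in H1975 alone, miR-205-3p and miR-203b-3p, the latter at least 1.87-fold higher there, although with normexp its value turned to 0.0032 and the mean of the 3 from -1.11 to 0.067. Of 6 blood cell markers 3 fell and 1 rose, with miR-150-3p at -1.39 and miR-146a-5p at 1.39, and their mean of -0.25 turned to 0.029 with normexp, where 2 fell and 3 rose. Of 5 mesenchymal and fibroblast markers 3 rose and 1 fell, with miR-10b-5p at 0.65, miR-152-3p at 0.42 and miR-22-5p at -1.06, and their mean of 0.043 turned to -0.37 with no scaling, where 1 rose and 2 fell. The 2 tested endothelial markers, miR-218-5p at -1.25 and miR-126-3p at -0.74, fell. Of 2 muscle markers 1 fell, miR-208a-5p at -0.12, but none fell when adjusted over the list alone, with median scaling, with the percentile over all miRNAs or with quantile normalization, and it turned to 0.063 with normexp and to 0.043 with the brightest probe. The endothelial, muscle and hypoxia lists were too short for the list test.

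Of the 8 miRNAs chosen in advance, miR-210-3p, which hypoxia induces, was at -0.97 (adjusted p = 1.91e-06, limma), let-7a-5p at -0.84, miR-200c-3p at -0.60 and miR-34a-5p, a p53 target, at -0.59. miR-222-3p rose by 0.72 (adjusted p = 6.82e-05, limma). miR-21-5p at -0.11 (adjusted p = 0.0699), miR-221-3p at 0.13 (adjusted p = 0.125) and miR-31-5p at -0.19 (adjusted p = 0.0551) did not pass limma's threshold, and in this order turned to 0.14 with the brightest probe, to -0.28 with no scaling and to 0.25 with quantile normalization. In the list of miR-221 and miR-222, 1 of 3 tested members rose and 1 fell, and its mean of 0.15 turned to -0.26 with no scaling. The 5 brightest miRNAs were miR-7975 at 0.21 and miR-7977 at 0.15, which were called higher and turned to -0.20 and -0.26 with no scaling, and miR-21-5p, let-7i-5p at -0.021 (0.14 with the brightest probe) and let-7e-5p at -0.012 (0.32 with quantile normalization), which were not called.

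Before scaling, the H1975_OR arrays were dimmer. Detected miRNAs numbered 1030 ± 19.5 (SD, n = 3) in H1975 and 917 ± 47.3 (SD, n = 3) in H1975_OR, and the 75th percentile used for scaling was 89.1 ± 1.22 and 66.9 ± 1.94 intensity units, a ratio of 0.751. Every H1975_OR array lay below every H1975 array in both measures (exact two-sided permutation test, p = 0.1 each, the smallest possible). The H1975_OR array on slide 1 had 864 detected miRNAs and a percentile of 68.0, and those on slide 2 had percentiles of 68.1 and 64.7.

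Across the 130 hairpins with both arms tested, the changes of the 5p and 3p arms had a Spearman correlation of 0.30 (permutation p = 8e-04) and a Pearson correlation of 0.29 (permutation p = 0.001), and 60.8% had the same sign. These correlations are across miRNAs, which are not independent replicates. For the 80 hairpins with both arms detected on all arrays the Spearman correlation was 0.22 (permutation p = 0.0521) and the Pearson correlation 0.24 (permutation p = 0.0329). Neighbouring miRNA genes had changes of the same sign in 51.5% of 767 pairs (permutation p = 0.199). By camera no chromosome of 23 was past the threshold with the preset correlation (lowest adjusted p = 0.822) or with an estimated one (0.981).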

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

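All tests in this part were chosen only after the results were seen. After scaling, 4 control probes, which the comparison of miRNAs did not use, had more signal on every H1975_OR array than on any H1975 array: hur_1 by 0.38, hur_2 by 0.38, hur_5 by 0.32 and mr_1 by 0.38 on the log2 scale. Their targets are not given in the sources used here. Before scaling the 6 bright control probes changed by -0.34 (hur_6) to -0.030 (hur_2).

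The pattern behind these values is the weaker miRNA signal on the H1975_OR arrays, whose 75th percentile was lower by a log2 change of -0.41. The mean unscaled change of the control probes was -0.11, less than that of the percentile, but hur_6 changed by -0.34. Their targets are not given. The log10 signals of the hybridisation and labelling spike-ins were identical, -0.70 on every array. They may be a floor value rather than a measured level, and they cannot show a change. Weaker hybridisation or scanning of the whole array can therefore not be decided. A difference between slides cannot be told apart from the groups, because only 1 H1975_OR array shared slide 1 with the H1975 arrays (its percentile was 0.763 of the H1975 mean). Less labelled RNA and a lower share of miRNA in the total RNA of the resistant cells cannot be told apart, because the labelling spike-in cannot show a change. The difference between resistant and parental cells stays open as a biological explanation.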

How the results depend on the processing

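Tests with slide 1 alone, scaling on control probes and miRNAs numbered under 1000 only were chosen only after the results were seen, and the other alternatives were fixed before the data were examined. The 697 calls (324 higher, 373 lower) had a count within 1.5 times under all 25 alternative fits, but their directions did not always hold. With no scaling there were 71 higher and 765 lower (9 and 154 by at least 2-fold), and 212 of the 697 calls turned sign. With scaling on bright control probes there were 79 and 626 (12 and 131), with normexp 700 and 206 (2 and 17) and 177 turned, and with the brightest probe the lower calls numbered 240 (45 by at least 2-fold). No scaling and control-probe scaling move every miRNA above the floor by a common amount on each array, so their shifts follow from the construction. The normexp setting changed the input to pixel medians and added an offset of 50, which were not tested apart, and the cause of the others was not tested. Lists past the threshold numbered 7, against 2 with quantile normalization, 2 with no scaling, 12 with normexp, 11 with the brightest probe, 1 with the authors' table, 4 for miRNAs detected on all 6 arrays, 14 with no filter, 3 of 26 among miRNAs numbered under 1000 only, 0 with an estimated correlation and 23 with fry, and the cause was not tested. The 3 were called higher: the DLK1-DIO3 cluster, the X-linked cluster and the miR-200 family (adjusted p = 0.00274, 0.0297 and 0.0481, and adjusted p = 0.851 each with an estimated correlation). The correlation of hairpin arms was 0.22 where both arms were detected on all arrays, with fewer hairpins. Leaving out each array gave 627 to 713 calls (291 to 365 higher, 332 to 358 lower; 20 to 26 and 68 to 82 by at least 2-fold), 7 to 9 lists and a difference in detected miRNAs of -131 to -85.7. Replicate numbers did not pair the samples (correlations of deviations -0.17, -0.068 and -0.0072), and with the replicate block 664 were called (311 higher, 353 lower), with 652 of the 697 kept. The real grouping gave 697 calls and the highest of the other splits gave 0, and 1 of the 10 splits gave as many, which are too few splits for a share under 0.05. Dim miRNAs are limited by signal over background, as values at the floor have no order.

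Values that turned sign were, on the log2 scale, the following. With quantile normalization, miR-31-5p 0.25, let-7e-5p 0.32. With no scaling, miR-221 and miR-222 (list mean) -0.26, X-linked miR-506 to miR-514 (list mean) -0.098, chromosome 14 DLK1-DIO3 cluster (list mean) -0.17, mesenchymal and fibroblast markers (list mean) -0.37, miR-29b-1-5p -0.24, miR-29a-3p -0.27, miR-302c-5p -0.28, miR-22-3p -0.15, miR-221-3p -0.28, miR-7975 -0.20, miR-7977 -0.26. With median scaling, let-7i-5p 0.010, let-7e-5p 0.019. With normexp, miR-181 family (list mean) 0.048, placental and stem cell clusters (list mean) 0.12, squamous and basal epithelium markers (list mean) 0.067, blood cell markers (list mean) 0.029, miR-205-3p 0.028, miR-6805-5p 0.053, miR-3692-5p 0.076, miR-33a-5p 0.033, miR-454-3p 0.022, miR-3065-5p 0.020, miR-6835-5p 0.0099, miR-628-5p 0.024, miR-34a-3p 0.030, miR-497-5p 0.0099, miR-29c-5p 0.016, miR-29a-3p -0.030, miR-181d-5p 0.12, miR-182-3p 0.018, miR-182-5p 0.098, miR-221-5p 0.0062, miR-99b-3p 0.086, miR-301b-3p 0.022, miR-519d-5p 0.042, miR-519e-3p 0.098, miR-7-1-3p 0.064, miR-203b-3p 0.0032, miR-95-3p 0.030, miR-219a-5p 0.029, miR-208a-5p 0.063, miR-4634 0.099, miR-200c-3p 0.086, miR-7977 -0.023. With the summed signal per miRNA, mesenchymal and fibroblast markers (list mean) -0.063. With the brightest probe, miR-181 family (list mean) 0.045, placental and stem cell clusters (list mean) 0.013, miR-208a-5p 0.043, miR-21-5p 0.14, let-7i-5p 0.14, let-7e-5p 0.073. With the authors' table, placental and stem cell clusters (list mean) 0.074, EGFR and MET regulated miRNAs (list mean) 0.11, miR-181d-5p 0.70, miR-182-5p 0.069, miR-7-1-3p 0.086, miR-486-3p 0.70, miR-200c-3p 0.70, miR-31-5p 0.23, let-7e-5p 0.18. With the flag for signal well above background, let-7i-5p 0.014, let-7e-5p 0.023. With control-probe scaling, miR-221 and miR-222 (list mean) -0.15, chromosome 14 DLK1-DIO3 cluster (list mean) -0.060, mesenchymal and fibroblast markers (list mean) -0.26, miR-29b-1-5p -0.13, miR-29a-3p -0.16, miR-302c-5p -0.16, miR-22-3p -0.034, miR-221-3p -0.17, miR-7975 -0.092, miR-7977 -0.15. With single arrays left out, let-7e-5p ranged from -0.029 to 0.028 and let-7i-5p ranged from -0.056 to 0.026. Beyond the common shifts and the effect of the normexp offset described above, the cause was not tested. Of the other comparisons of a named miRNA with an alternative, 2898 kept direction and call, 102 lost the call and 33 gained it, and for lists these were 595, 31 and 31.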

Other observations

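All tests in this part were chosen only after the results were seen, except those of hairpin arms, of all neighbouring genes and of chromosomes, which were fixed before the data were examined and whose predictions were written afterwards.

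Neighbouring miRNA genes under 10 kb apart had changes of the same sign in 70.8% of 96 pairs (permutation p = 1e-04, the smallest that 10000 draws can give), and those further apart in 48.7% of 671 pairs (p = 0.751). This is consistent with neighbours that share a transcript, as a hypothesis found on the same data. The arms of a hairpin moved together with a Spearman correlation of 0.30, which a shared hairpin may explain and which was 0.22 where both arms were detected on all arrays. A whole chromosome that differs between the lines was not seen, with a lowest adjusted p of 0.822 by camera, which does not exclude smaller regions.

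miRNAs with a registry number under 1000, most of them long known, had a median change of -0.17 (374 tested, 84 higher and 189 lower), and those numbered 1000 or above had one of 0.047 (624 tested, 240 higher and 184 lower). In 5 groups of rising signal, the medians of those under 1000 were -0.18, -0.046, 0.00093, -0.14 and -0.41. Those of the others were -0.0085, 0.088, 0.0096, 0.043 and 0.089. The classes thus differed most among the brightest miRNAs and hardly at middle signal. Leftover background in dim probes is argued against by the brightest 20% of miRNAs, where the medians differed by -0.50. The bootstrap 95% interval was -0.70 to -0.34, and the 1-sided permutation p was 1e-04, the smallest possible. Both treat miRNAs as independent, which members of a family or cluster may not be, and neither measures the spread between samples. The difference of -0.36 that remained with normexp, another background correction, argues against leftover background too. A difference between slides cannot be told apart, because slide 1, where the value was -0.54, held only 1 H1975_OR array. GC content of the probes stays open, since the 19 miRNAs of the GC-rich list among them had a median of -0.14, between those of the other miRNAs numbered 1000 or above (0.20) and of those under 1000 (-0.41), and probe sequences were not used here. A lower level of long-known miRNAs in the resistant cells is a further open explanation, untested.

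The clusters of the miR-200 family moved apart. A difference between slides cannot be told apart from the groups, because the 2.57 between the clusters' changes on slide 1 rests on 1 H1975_OR array. Over 25 alternatives miR-141-3p lay between -1.09 and -0.11 and the dim miR-200c-3p between -1.01 and 0.70. In the other cluster miR-200b-3p lay between 1.54 and 2.23, miR-200a-3p between 0.60 and 2.34 and miR-429 between 0.30 and 2.59. Separate regulation of the clusters in resistant cells may be a candidate explanation and was not tested.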
